A study of Homo sapiens with 6 samples.

How the data were processed

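Ribosome footprint libraries of RKO cells were compared, 3 with a control short hairpin RNA and 3 with a hairpin against TRMT6. Per the labels' protocols, lysate was digested with RNase I and DNase I, protected fragments above 17 nt were purified over size exclusion columns, and libraries were made with a small RNA kit. The values are FPKM per gene as the authors deposited them, per the file headers, rounded to 2 decimals. The submitters' processing notes name fastp, STAR and RSEM without versions or roles. The genome build and the annotation are not given in the sources used here. How reads from near-identical genes were divided, whether strand was used and whether ribosomal RNA reads were removed are likewise not given, and each could change the values of histone copies, overlapping genes and the mitochondrial share. FPKM is relative to the library, so a large rise in a few genes lowers the others. No RNA-seq of the same cells was used here, so ratios of footprints to mRNA were not computed.

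Columns were assigned to samples by name. The table has columns named NC and SH, each numbered 1 to 3, and the samples are shControl and shTRMT6 replicates 1 to 3. NC was read as the control and SH as the knockdown, which no label spells out, and 0 columns were left unassigned. The table has 20289 genes under Ensembl identifiers, of which 6397 are at 0 in every library. Symbols were found for 19705 identifiers in the gene name table, and 584 had none. Positions, coding lengths and codon use came from GENCODE 29 on GRCh38, which holds 20171 of the identifiers and may differ from the authors' annotation.

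FPKM holds no counts, but low values fall on steps. For 4207 genes with a single coding transcript, FPKM times coding length in GENCODE 29 gave the value of 1 read, from 0.245 to 0.390 FPKM for a coding length of 1 kb, and from it an estimated 2567000 to 4082000 reads per library. Of the low values used, 68.5% to 78.3% came within 0.1 of a whole number of reads, against 22.1% to 47.8% with transcript length. These totals are estimates, and count models were not fitted. At this depth a gene of 1 kb with 1 FPKM rests on about 3 to 4 reads, so low genes are imprecise.

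The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with group as the only term and eBayes with an intensity trend, over 11566 genes with at least 1 FPKM in at least 3 libraries. Benjamini-Hochberg adjusted p under 0.05 was the threshold. Fold changes are on the log2(FPKM + 1) scale and understate the change of low genes. No 2 libraries were duplicates. Before the data were examined, 32 gene lists were fixed, of which 30 had at least 5 tested genes. They were tested with camera at a correlation of 0.01, two-sided, adjusted over the 30 lists, and with fry. Camera compares a list with all other genes, while fry does not. With the correlation estimated from the data, 0 of the 30 lists passed camera, 6 had an unadjusted p under 0.05, and fry passed 13. Shares are percent of each library's FPKM sum, tested by exact permutation, where 3 against 3 gives no p under 0.1.

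Named genes followed a rule fixed before the data were examined. TRMT6 comes before all others and TRMT61A is always named. Then come the 10 largest increases and 10 largest decreases among genes past the threshold with a symbol, with non-overlapping groups and a mean above the median of tested genes. Of the called genes, 1266 higher and 892 lower met these criteria. From each list that passed, and from the histone, ATF4, p53 and S phase lists in any case, up to 4 members with the smallest p in the direction of the list were taken, and the text gives at least 2 of them; some genes are not reported here. All other genes were named after their values were seen.

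The fit was tested on simulated data of 11491 genes with the spread of the real genes, for the comparison of shTRMT6 with shControl. Of 100 genes changed 2-fold it recovered 12%, and of 100 changed 4-fold 69%, with the correct sign in 100% of both. Of 85 calls 4 were false. Only 200 simulated genes were changed, none of them among the genes of lowest level. The noise was independent between genes, with no slope by level or length and no shift of all genes. The real comparison called 4115 genes, so the recovery and the share of false calls do not carry over to it. Alternatives fixed in advance were median scaling, no low-value filter, a mean of at least 5 FPKM, a pseudocount of 0.1, the replicate number as a block, other thresholds, other list tests and leaving out each library in turn. Share of the library sum, quantile normalization and removal of the trends with level and coding length (splines with 5 degrees of freedom, fitted per library) were added after seeing the data. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.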

Results

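Ribosome footprints, the stretches of mRNA that a translating ribosome shields from nuclease, were sequenced from RKO cells, a human colorectal cancer cell line. The 6 libraries form 2 groups of 3, cells with a control short hairpin RNA (shControl) and cells in which the hairpin targets TRMT6 (shTRMT6). TRMT6 forms with TRMT61A the enzyme that methylates adenosine 58 of cytosolic tRNAs to m1A. The title of the series names histone production as the subject, and the comparison asks which mRNAs carried more or fewer ribosomes after knockdown. Footprint level is a product of mRNA amount and ribosomes per mRNA, which these values alone do not separate. The deposited FPKM summed to 1463000 to 1760000 in the control libraries and 1532000 to 1583000 in the knockdown libraries. The steps between low values gave an estimate of 2608000 to 3906000 reads on coding sequence per control library and 2567000 to 4082000 per knockdown library. Genes with a value above 0 numbered 11879 to 12037 in the control libraries and 12632 to 12730 in the knockdown libraries. Across genes, Pearson's r of log values was 0.944 to 0.967 within a group and 0.896 to 0.940 between groups. The labels do not say that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries.

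TRMT6 footprints were lower in every knockdown library than in every control library. TRMT6 (ENSG00000089195, protein-coding, minus strand of chromosome 20 from 5937235 to 5950558 in GENCODE 29, GRCh38) had 57.6, 58.4 and 95.3 FPKM in the control libraries and 20.7, 21.9 and 24.1 FPKM in the knockdown libraries. The means were 70.4 ± 21.5 and 22.2 ± 1.73 FPKM (SD, n = 3 each). The log2 fold change of FPKM + 1 was -1.58 (SE 0.27, limma adjusted p = 0.00301). Its partner TRMT61A (ENSG00000166166, plus strand of chromosome 14 from 103529184 to 103537073) had a log2 fold change of -0.66 (SE 0.31), which did not pass (limma adjusted p = 0.122). With each library scaled to its median, TRMT61A had a log2 fold change of -1.14 and an adjusted p of 0.0205.

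**Figure D1:**
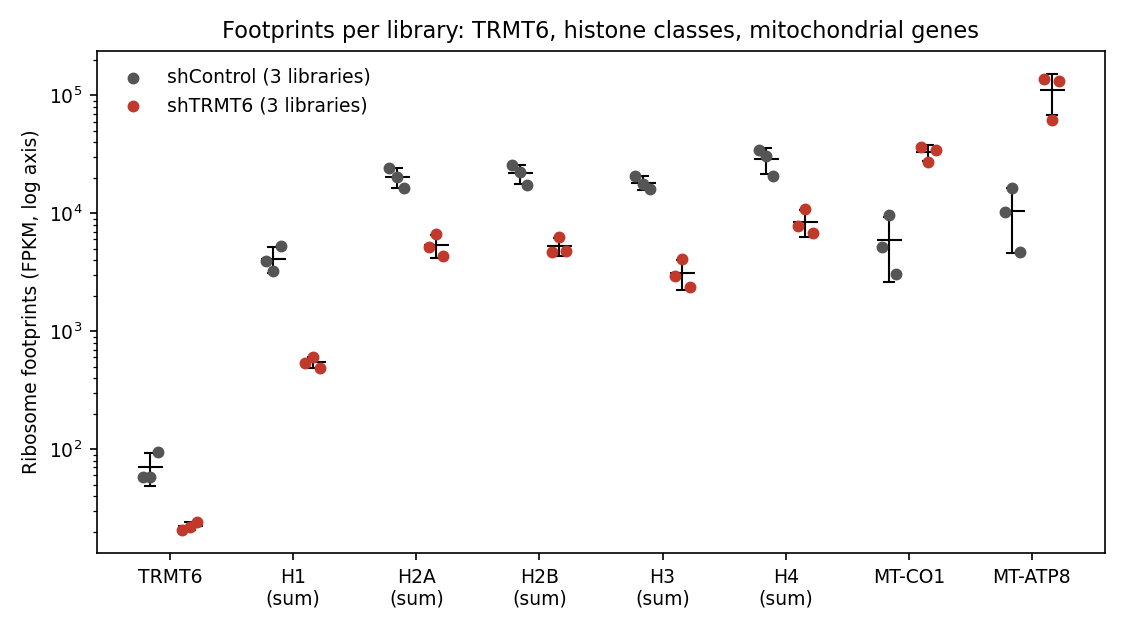
Footprint level in FPKM on a log axis in each of the 6 libraries (points; bars are mean and SD, n = 3 per group) for TRMT6, for the summed replication-dependent genes of the 5 histone classes and for MT-CO1 and MT-ATP8. For each item the groups do not overlap; TRMT6 and the histone sums are lower in shTRMT6, and both mitochondrial genes are higher.

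Replication-dependent histone genes, which encode the bulk of new chromatin protein in S phase and lie mostly in clusters on chromosomes 6 and 1, had far fewer footprints after knockdown. Of 54 tested members 51 were lower, and the other 3 did not pass. Adjusted over the list alone, 52 were lower, and with median scaling 53 were. The summed FPKM of the 63 genes in the table was 93071 ± 16553 in shControl and 22780 ± 5149 in shTRMT6 (SD, n = 3 each), 4.09-fold lower. The linker histone class H1 was 7.57-fold lower, from 4135 ± 1023 to 546 ± 56.9 FPKM (SD, n = 3 each), with 3 of 3 tested genes lower. Among the core histones, which form the nucleosome, the H3 sum was 5.78-fold lower with 10 of 11 genes passing. The H2B sum was 4.17-fold lower with 15 of 15, the H2A sum 3.77-fold lower with 11 of 13, and the H4 sum 3.38-fold lower with 12 of 12. H1-3 went from 705 ± 127 to 68.9 FPKM (log2 fold change -3.32, SE 0.22, limma adjusted p = 0.00015). H3C1 went from 690 ± 26.4 to 80.7 FPKM (log2 fold change -3.09), H3C2 from 2813 ± 380 to 417 FPKM (-2.75) and H1-2 from 1436 ± 262 to 218 FPKM (-2.70).

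Histone copies are nearly identical, and H3C14 with H3C15 and H4C11 with H4C12, named after their values were seen, had identical values in every library, so single copies are less certain than class sums. The median log2 fold change of the list was -2.01, and -2.49 with median scaling. The list lay lower than the other genes (camera with a correlation of 0.01, adjusted p = 9.83e-47), but did not pass with the correlation between its genes estimated (adjusted p = 0.234 with an estimated correlation). The second list test, fry, which asks whether the members differ between the groups in a common direction, gave an adjusted p of 0.00665. Replication-dependent histones held 5.60% ± 0.52 of the FPKM sum in shControl and 1.46% ± 0.31 in shTRMT6 (SD, n = 3 each; two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows).

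Some histone genes expressed outside S phase were also lower, and the median change of their list was smaller. Of 10 tested replication-independent histone genes 5 were lower and 5 did not pass, with a median log2 fold change of -0.72. The H3.3 genes H3-3B and H3-3A had log2 fold changes of -1.55 and -1.51, the H2A variants H2AZ1 and H2AX -1.40 and -1.23, and H1-10, named after its value was seen, also passed. With median scaling 7 were lower. As a list they passed (camera adjusted p = 6.27e-05; adjusted p = 0.121 with an estimated correlation). Among 31 genes of histone mRNA processing and histone chaperones 9 were higher and 3 lower, while with median scaling 3 were higher and 8 lower, and the list did not pass (camera adjusted p = 0.736). The 3 genes lower without scaling, named after their values were seen, were SLBP, which binds the stem-loop of histone mRNAs, the chaperone ASF1B and the cleavage factor CSTF2. SLBP had 191 ± 44.9 FPKM in shControl and 107 ± 7.61 FPKM in shTRMT6 (SD, n = 3 each; log2 fold change -0.80).

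Footprints on mRNAs encoded by mitochondrial DNA were higher after knockdown. All 12 tested genes rose, with a median log2 fold change of 2.67, and 12 rose with median scaling. MT-CO3, a subunit of cytochrome c oxidase, went from 877 ± 316 to 5365 FPKM, MT-CO2 from 1085 ± 503 to 7958 FPKM and MT-ND4, a complex I subunit, from 366 ± 168 to 2191 FPKM. The class held 1.33% ± 0.63 of the FPKM sum in shControl and 11.6% ± 3.32 in shTRMT6 (SD, n = 3 each; two-sided exact permutation p = 0.1, the smallest possible). MT-ATP8, which overlaps MT-ATP6 so that reads can be shared, had 10477 ± 5881 FPKM in shControl and 110310 in shTRMT6. Without MT-ATP8 the share was 0.716% ± 0.318 against 4.47% ± 0.537, 6.23 times higher. The 12 genes passed as a list (camera adjusted p = 7.71e-08; adjusted p = 0.473 with an estimated correlation). Single control libraries held 0.79% to 2.02%, and single knockdown libraries 7.74% to 13.7%.

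Across 11566 tested genes, 3069 were higher and 1046 lower in shTRMT6 (limma, adjusted p under 0.05), of which 66 have no symbol. The median log2 fold change of all tested genes was 0.39. With each library scaled to its median, 1449 genes were higher and 2260 lower. Of the calls made without scaling, 1449 higher and 1046 lower genes kept their direction and their call. This scaling lowers every log2 fold change by the same amount and took the median of all tested genes to -0.09. That the lower calls held was thus nearly fixed in advance. Without shTRMT6 replicate 1, 2 or 3 the total of 4115 genes was 2471, 2742 or 2370. The lower genes numbered 590 without shTRMT6 replicate 1, 601 without shTRMT6 replicate 3 and 689 without shControl replicate 1. Genes with non-overlapping groups made up 51.4% of those tested, where chance gives 10%. The change followed footprint level and length. In 10 bins by mean level the median log2 fold change went from 0.74 in the lowest bin to -0.39 in the highest. In 8 bins by coding length it went from -0.10 at a median length of 411 nt to 0.88 at 4086 nt.

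**Figure D2:**
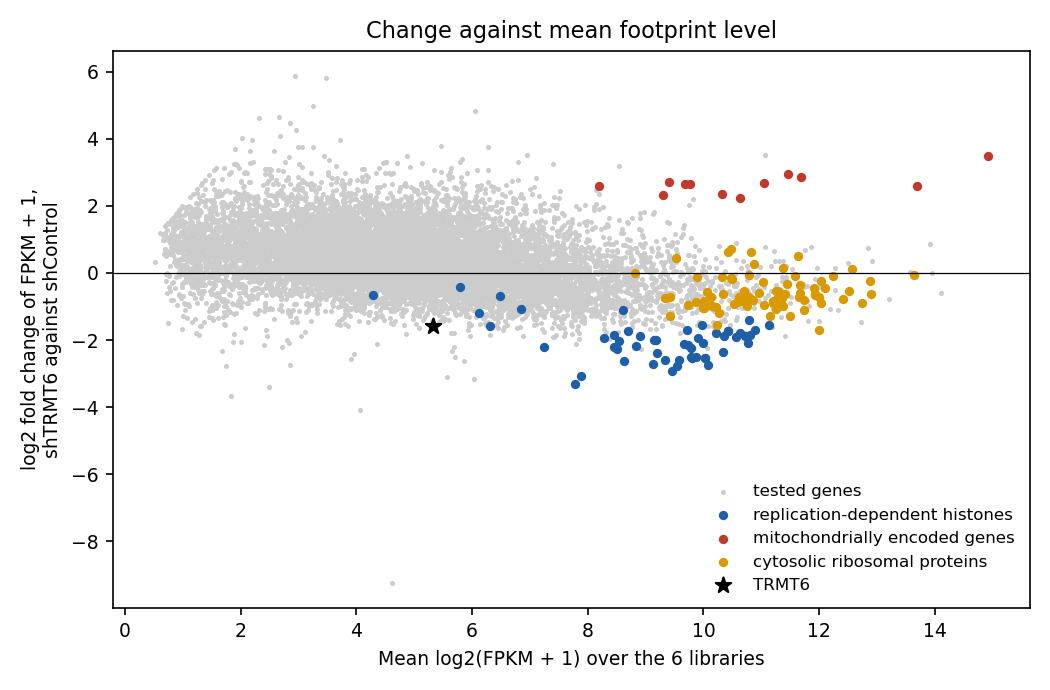
Log2 fold change of FPKM + 1 (shTRMT6 against shControl, n = 3 each) against mean log2(FPKM + 1) over the 6 libraries, 1 point per tested gene, with replication-dependent histones, cytosolic ribosomal proteins, mitochondrially encoded genes and TRMT6 in colour. Histones lie around their median of -2.01, mitochondrially encoded genes around 2.67, and the cloud of all genes slopes down towards high levels.

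The gene with the largest increase among those named was TTLL3, a tubulin glycylase, at 15.9 ± 15.4 FPKM in shControl and 353 in shTRMT6 (log2 fold change 4.84, SE 0.58). TAF1D, a subunit of the RNA polymerase I selectivity factor, went from 739 ± 499 to 7453 FPKM (3.52). The zinc finger genes ZNF112 and ZNF432 had log2 fold changes of 3.80 and 3.53, the phospholipase DDHD1 3.77, the Ral exchange factor RALGDS 3.39 and the chromatin remodeller CHD2 3.30. MT-ATP8 (3.48), NPIPB3 (3.49) and AGAP6 (3.31) complete these 10. All of them but ZNF112 had their highest control value in shControl replicate 2, for example 33.2 FPKM for TTLL3 against 3.58 and 10.9. That library had a Pearson's r of 0.929 to 0.940 with the knockdown libraries, and of 0.967 and 0.944 with shControl replicates 1 and 3. These genes thus also varied among control libraries. NPIPB3 and AGAP6 belong to families of near-identical copies, so their reads are uncertain. The 10 largest decreases were taken, by the rule, only among genes with a mean above the median of tested genes. Of these 10, 9 were replication-dependent histones, H1-3, H3C1, H1-4, H3C4, H3C2, H1-2, H2AC4, H2BC10 and H4C9, between -3.32 and -2.59. The other was DEGS1, the desaturase that makes ceramide, which fell from 194 ± 9.94 to 21.2 FPKM (log2 fold change -3.16, SE 0.23, limma adjusted p = 0.000333).

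Of 79 cytosolic ribosomal protein genes 45 were lower and 1, RPLP0, named after its value was seen, higher (50 lower and 4 higher adjusted over the list alone), with a median log2 fold change of -0.72. RPS3 went from 7328 ± 120 to 2275 FPKM (-1.69), RPL29 from 2069 ± 74.7 to 705 FPKM (-1.55), and RPS7 and RPL18 had log2 fold changes of -1.27 and -1.29. With median scaling 60 members were lower. Their share of the FPKM sum was 15.4% ± 0.557 in shControl and 11.03% ± 0.695 in shTRMT6 (SD, n = 3 each; two-sided exact permutation p = 0.1, the smallest possible). RPLP0 (0.64) did not pass with median scaling (0.16, adjusted p = 0.563). The list passed (camera adjusted p = 3.27e-19; adjusted p = 0.234 with an estimated correlation). Its call ended with quantile normalization (adjusted p = 0.167) and with the trends with level and length removed (adjusted p = 0.0523).

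Of 78 mitochondrial ribosomal protein genes 39 were lower and 39 did not pass (43 lower adjusted over the list alone and 61 with median scaling; median log2 fold change -0.72). MRPL16 went from 335 ± 10.6 to 91.5 FPKM (-1.86), and MRPL48, MRPS17 and MRPS28 had log2 fold changes of -1.87, -1.64 and -1.56. The list passed (camera adjusted p = 3.27e-19; adjusted p = 0.144 with an estimated correlation). Nuclear genes for oxidative phosphorylation subunits had 34 of 71 members lower and 1, UQCR11, named after its value was seen, higher (37 and 1 over the list alone, and 50 lower with median scaling, where UQCR11 did not pass), opposite in direction to the mitochondrially encoded subunits. The ATP synthase genes ATP5MC1 and ATP5MC3 had log2 fold changes of -2.11 and -1.60, UQCRFS1 of complex III -1.40 and NDUFV2 of complex I -1.20. The median was -0.70 (camera adjusted p = 7.66e-16; adjusted p = 0.344 with an estimated correlation), against -0.41 with quantile normalization and -0.36 with trends removed, where the list still passed (adjusted p = 0.00615 and 0.00141). In the proteasome list 24 of 36 genes were lower and 1, PSMD13, named after its value was seen, higher (25 and 1 over the list alone, and 30 lower with median scaling, where PSMD13 did not pass). The catalytic subunits PSMB5, PSMB6 and PSMB7 had log2 fold changes of -1.76, -1.58 and -1.50, and PSMA2 -1.80. The median was -0.90 (camera adjusted p = 1.94e-15; adjusted p = 0.234 with an estimated correlation).

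A part of the targets of p53, which are induced by DNA damage and other stress, was higher. Of 33 tested members 17 were higher and 16 did not pass, also over the list alone, with a median log2 fold change of 0.79. TP53INP1 went from 16.4 ± 1.40 to 115 FPKM (2.71), MDM2, the ubiquitin ligase of p53, from 104 ± 3.89 to 350 FPKM (1.73), and PLK3 from 6.04 ± 1.17 to 34.7 FPKM (2.34). DDB2, a DNA damage sensor, had a log2 fold change of 1.36. CDKN1A, named after its value was seen, had 0.38 and did not pass. With median scaling 6 members were higher and 1, FBXO22, named after its value was seen, lower, with a median of 0.31. The p53 list passed (camera adjusted p = 0.000319; adjusted p = 0.121 with an estimated correlation).

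Genes of DNA replication and S phase moved both ways. Of 57 tested, 14 were lower and 5 higher, also over the list alone, with a median log2 fold change of -0.22. With median scaling 24 were lower and 2 higher. DUT went from 456 ± 33.8 to 117 FPKM (-1.96), TYMS, thymidylate synthase, from 278 ± 10.9 to 81.8 FPKM (-1.75), and the sliding clamp PCNA from 891 ± 313 to 299 FPKM (-1.52). The 5 higher genes, named after their values were seen, were E2F1, RFC1, POLD2, DNMT1 and POLE. The list lay below other genes (camera adjusted p = 0.000211; adjusted p = 0.556 with an estimated correlation) but did not pass fry (adjusted p = 0.535), and its call ended without shControl replicate 3 (adjusted p = 0.104, median 0.03).

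In the G2 and mitosis list 6 of 46 genes were lower and 7 higher, also over the list alone, while with median scaling 18 were lower and 3 higher. The 7 higher without scaling, named after their values were seen, were FOXM1, BUB1B, MKI67, ANLN, HMMR, ASPM and TPX2. The lower ones included the securin PTTG1 (-1.89), the checkpoint gene MAD2L1 (-1.82), CDK1 (-1.54) and UBE2C (-1.35). The median was -0.01 and the list lay below other genes (camera adjusted p = 0.0203; adjusted p = 0.571 with an estimated correlation; fry adjusted p = 0.750). Its call ended without shControl replicate 3 (adjusted p = 0.359) and without shTRMT6 replicate 2 (adjusted p = 0.0531).

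Targets of ATF4 and the integrated stress response did not pass as a list (camera adjusted p = 0.352). Of 32 tested 9 were higher, DDIT3, PPP1R15A, DDIT4, CEBPB, ATF5, SESN2, SLC38A2, ATF3 and SLC7A11, named after their values were seen, and 2 lower, also over the list alone. With median scaling the balance turned, with 3 higher and 11 lower. The median was -0.13 and the mean 0.19, and the tests pointed opposite ways, camera down and fry up (fry adjusted p = 0.0308). Unlike camera, fry makes no allowance for the upward shift of all tested genes. PSAT1, a serine synthesis enzyme, went from 55.1 ± 14.3 to 14.5 FPKM (-1.83), and CEBPG had a log2 fold change of -0.83. CEBPG lost its call in 5 of the 6 fits that left out 1 library, all but that without shControl replicate 3, with adjusted p-values up to 0.105. CHAC1 (-1.56, adjusted p = 0.0607) and PSPH (-0.65, adjusted p = 0.0658) did not pass. Both passed without shControl replicate 3 (adjusted p = 0.0313 and 0.0424) and with median scaling, quantile normalization or trends removed. CHAC1 is a low gene and so imprecise, at 13.8, 3.04 and 2.12 FPKM in the control libraries and 0.53, 1.77 and 0.71 in the knockdown libraries. DDIT3, the stress factor CHOP, went from 16.5 ± 12.5 to 119 ± 25.6 FPKM (SD, n = 3 each; log2 fold change 3.08, limma adjusted p = 0.00313).

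Cholesterol biosynthesis genes and SREBP targets had 9 of 32 members lower and 4 higher, also over the list alone, with a median of -0.49. With median scaling 16 were lower and 1 higher. ACAT2 (-1.58), MSMO1 (-1.24) and EBP (-1.23) were lower, and SREBF1, which encodes an SREBP factor, MVD, TM7SF2 and STARD4, named after their values were seen, were higher. The list passed (camera adjusted p = 0.000132; adjusted p = 0.121 with an estimated correlation). Heat shock genes and cytosolic chaperones had 5 of 29 members lower and 2, HSF1 and HSPH1, named after their values were seen, higher (4 and 1 over the list alone), and with median scaling 11 were lower and none higher. The chaperonin subunits CCT7 and CCT8 had log2 fold changes of -1.77 and -1.26 and DNAJB6 -1.09, and AHSA1, and CCT2, named after its value was seen, were also lower (camera adjusted p = 0.00127; adjusted p = 0.571 with an estimated correlation; fry adjusted p = 0.576). The heat shock list lost its call with quantile normalization (adjusted p = 0.529) and with trends removed (0.146). AHSA1 lost its call without shTRMT6 replicate 2 or 3 (adjusted p = 0.0841 and 0.0798) and with quantile normalization (0.120), and DNAJB6 and AHSA1 lost theirs with trends removed (-0.76, adjusted p = 0.0650, and -0.51, 0.0900). Genes of glycolysis and hypoxia had 7 of 32 lower and 5 higher, VEGFA, PFKL, PFKM, PFKFB3 and NDRG1, named after their values were seen, also over the list alone, and with median scaling 9 were lower and 1 higher. The glycolytic enzymes PGAM1 and TPI1 had log2 fold changes of -1.51 and -1.31 and the mitophagy receptor BNIP3L -1.23 (camera adjusted p = 0.0203; adjusted p = 0.556 with an estimated correlation; fry adjusted p = 0.564). This list lost its call with quantile normalization (adjusted p = 0.174) and with trends removed (0.0902).

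Translation initiation factors had 9 of 40 members lower and 5 higher (10 and 7 over the list alone), the latter PABPC1, EIF4A2, EIF4G1, EIF4B and EIF5B. With median scaling 18 were lower and 4 higher. EIF3I, EIF4H and EIF3F had log2 fold changes of -1.14, -1.06 and -0.996. The median was -0.01, the mean 0.03 and the test pointed down (camera adjusted p = 0.0281; adjusted p = 0.556 with an estimated correlation; fry adjusted p = 0.750). With quantile normalization its direction turned up (adjusted p = 0.853), and its call also ended with trends removed (0.890) and with a mean of at least 5 FPKM (0.0525). Aminoacyl-tRNA synthetases and their cofactors had 3 of 23 members lower and 1, QARS1, higher, also over the list alone, and with median scaling 8 were lower and 1 higher. AIMP2, a scaffold of the synthetase complex, had a log2 fold change of -1.42 and the tryptophan enzyme WARS1 -0.998, and WARS1 lost its call without shTRMT6 replicate 3 (-0.88, adjusted p = 0.0752). GARS1 (-1.16) lost its call without shTRMT6 replicate 1 or 2 (adjusted p = 0.0642 and 0.0656). The higher genes of both lists were named after their values were seen. The list passed (camera adjusted p = 0.0281; adjusted p = 0.583 with an estimated correlation; fry adjusted p = 0.750), but not with quantile normalization (adjusted p = 0.269). Without shControl replicate 3, the initiation factor, synthetase, glycolysis and heat shock lists lost their calls (adjusted p = 0.225, 0.620, 0.198 and 0.226). Without shTRMT6 replicate 2 the first and second of these did (adjusted p = 0.0634 and 0.0546).

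**Figure D3:**
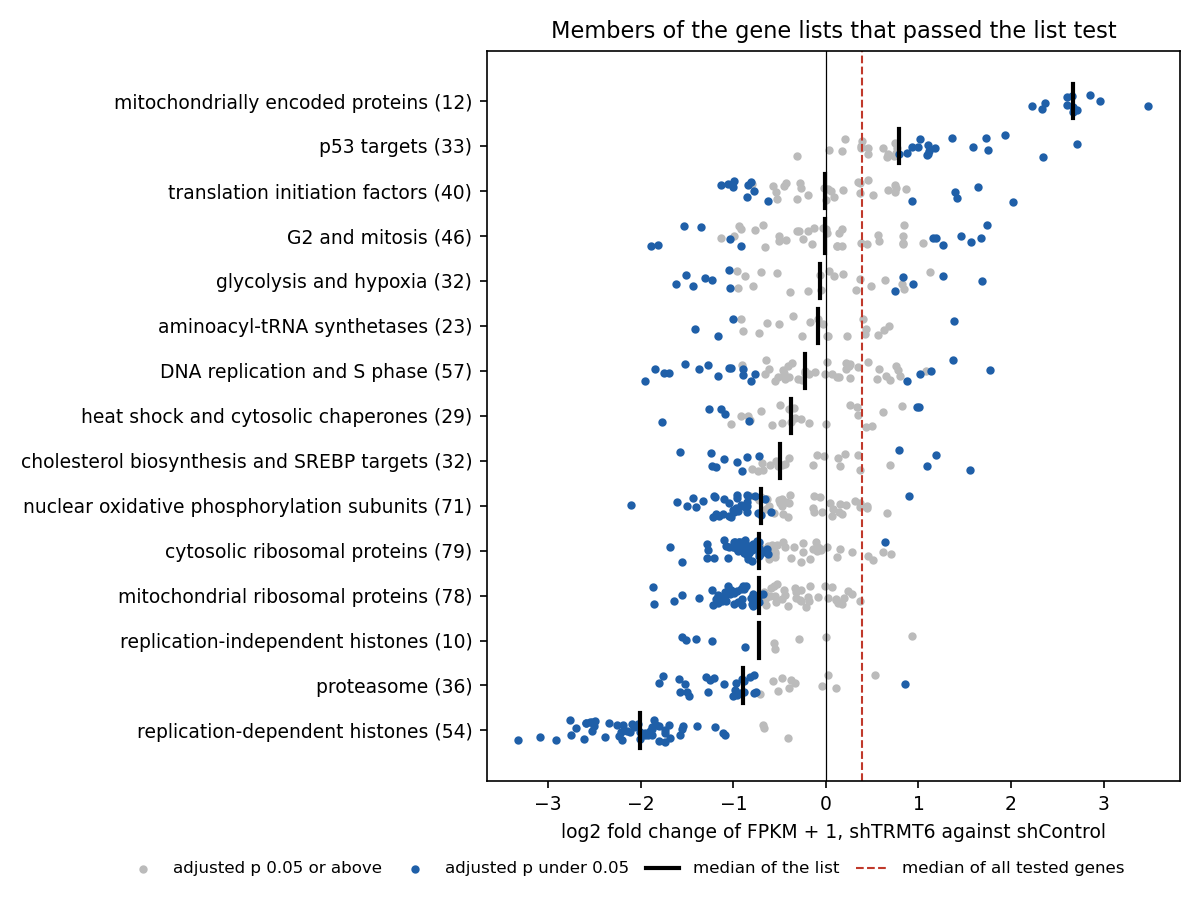
Log2 fold change of FPKM + 1 (shTRMT6 against shControl, n = 3 each) of each member, 1 point per gene, of the 15 gene lists that passed camera with a correlation of 0.01, with the number of tested genes in parentheses; thick lines are list medians and the dashed line is the median of all tested genes, 0.39. Replication-dependent histones have a median of -2.01 and mitochondrially encoded genes of 2.67, while lists with medians near 0 have members on both sides.

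The other lists did not pass camera, and their genes were named after the values were seen. Fry passed 3 of them as higher, the NF-kB list (fry adjusted p = 0.00815), immediate early genes (0.0110) and other tRNA modification enzymes (0.0318). Fry tests a list against no change, and the median of all tested genes was 0.39, so a list of ordinary genes can pass as higher. The tRNA modification list had a median of 0.25, below that of all genes, and -0.23 with median scaling. The NF-kB and immediate early lists had medians of 0.61 and 0.70, and 0.13 and 0.22 with median scaling. Among 25 genes of the unfolded protein response the ER folding genes PDIA3, PDIA6 and DNAJB11 and the translocon subunit SEC61B were lower and CRELD1 higher (camera adjusted p = 0.0537). That list passed with median scaling (7 lower, 1 higher, adjusted p = 0.0136), with no low-value filter (0.0426) and without shControl replicate 2 (0.0372). Of 40 genes of autophagy and the lysosome 5 were higher (WIPI1, ATG16L1, BECN1, GABARAPL1 and ULK1) and 2 lower (ATG5 and ATP6V0D1; adjusted p = 0.171), and with median scaling 2 were higher and 11 lower and the list passed (0.0424). The inflammatory genes LIF, CSF1, CXCL2, CXCL8 and BIRC3 were higher, 5 of 16 in the NF-kB list (adjusted p = 0.278). Immediate early genes had 8 of 24 higher, with FOS, JUND, KLF6 and ZFP36 among them, and SPRY4 lower (0.433). NKD2 and CCND1 were higher among 13 Wnt targets (0.433). Of 29 interferon-stimulated genes TRIM22, STAT2, IRF9 and SAMD9 were higher and CXCL10, IFITM1, IFI6 and ISG15 lower (0.318). The ferritin genes FTL and FTH1, OSGIN1 and SLC7A11 were higher and TALDO1, GSR and PGD lower among 18 NRF2 targets (0.398). Of 14 tRNA m1A writers, erasers and readers YTHDF1 and YTHDC1 were higher and TRMT6 and ALKBH7 lower (0.352). Among other tRNA modification enzymes 16 of 56 were higher and 1, TRDMT1, lower (0.567), while with median scaling 8 were higher and 10 lower. The list of elongation and termination factors, with 20 tested genes, also holds genes that are not such factors. In it ZNF598, GTPBP2, ASCC3, NEMF and EEF2K, none of them such a factor, were higher and EIF5A and EEF1B2 lower (0.398). MYC targets and ribosome biogenesis had 10 of 48 higher and 7 lower (0.570), against 3 higher and 12 lower with median scaling. Of 16 mesenchymal genes 2 were higher and 2 lower (0.555), and of 7 tested epithelial and intestinal genes none passed (0.433). With median scaling the interferon and NRF2 lists each had 3 higher and 7 lower, and the elongation factor list 2 and 7. Immediate early genes then had 3 and 4, the m1A list 1 and 4 and mesenchymal genes 1 and 3. The NF-kB list then had 3 higher, Wnt targets 1 higher and the epithelial list 1 lower. Blood and immune markers had 1 tested gene of 18, and fibroblast and endothelial markers 2 of 15, with COL6A1 higher, too few for a test. Camera pointed down, without passing, for the unfolded protein response, autophagy, interferon, NRF2, mesenchymal, MYC and histone processing lists, whose medians were above 0. The elongation factor and m1A lists had medians below 0 and means above it, and so had the epithelial list.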

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

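Share of the library sum, quantile normalization and trend removal were chosen after seeing the data. TRMT6 kept its direction and call under every alternative run (log2 fold change -2.07 to -1.35), and so did the histone list with camera at a correlation of 0.01 (-2.49 to -1.61). With an estimated correlation the histone median is the same -2.01 but the adjusted p was 0.234. In that setting 0 of 30 lists passed camera in place of 15, and 6 had an unadjusted p under 0.05. Fry passed 13, of which 9 among the 15. An estimated correlation allows for genes that move together, but this is not the whole difference. The p53 list had an estimated correlation of -0.017, below the preset 0.01. Its unadjusted camera p still went from 0.000106 to 0.0112. Scaling moved the split of the 4115 calls: 1449 higher and 2260 lower with median scaling, 1602 and 1700 with quantile normalization, 1543 and 1563 with trends removed, 3487 and 954 as shares of the library sum; the cause was not tested beyond the shift of 0.39 in the median of all genes. Stricter thresholds gave 1894 genes (1421 higher, 473 lower) at adjusted p under 0.01 and 561 lower genes at a log2 change above 1 in size. As percentage points of nuclear genes without ribosomal proteins the histone share changed by -4.86 in place of -4.15. The control share was then 6.74% in place of 5.60%, and the relative fall was slightly smaller, 3.59-fold in place of 3.84-fold.

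Leaving out each library gave 2370 to 4717 called genes, 1769 to 3290 higher and 590 to 1427 lower. Totals moved by over 1.5 times without shTRMT6 replicate 1, 2 or 3 (2471, 2742 and 2370), as did higher genes (1881, 2018 and 1769). Lower genes did so without shControl replicate 1 (689), shTRMT6 replicate 1 (590) or 3 (601). Each fit had 1 library fewer, but that alone does not set the totals, which were 4097 and 4717 without shControl replicates 2 and 3. List calls ran from 9, without shControl replicate 3, to 16. TRMT6 ran from -1.70 to -1.35, the histone median from -2.16 to -1.89, and the shares by -4.35 to -3.85 points (histones), -4.82 to -4.21 (ribosomal proteins) and 9.14 to 12.1 (mitochondrial).

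For 81 other named genes, 1097 alternatives kept direction and call, 20 lost and 15 gained a call. AHSA1, CEBPG, DNAJB6, EIF4E, GARS1, SLC16A3 and WARS1 lost it somewhere, and CHAC1, EEF1E1, PSPH and TRMT61A gained it. The replicate block gave 4211 genes in place of 4115, 3146 higher and 1065 lower, with 15 lists. Correlations of same-numbered libraries' deviations were 0.012, 0.0134 and 0.102, so the numbers were not taken to pair the libraries, and number 1 correlated better with another number (0.127). DESeq2-style size factors, library totals, DESeq2 and limma-voom were planned for counts and not run, since the values are FPKM. Depth limits low genes, where 1 read in 1 kb is 0.245 to 0.390 FPKM.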

Other observations

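The tests of GC content and codon use were set before their results were computed, but rest on the trend removal chosen after seeing the data. No prediction set in advance is given for the comparison by retained introns. All other tests in this part, and the 3 gene lists of the next paragraph, were chosen after the values were seen.

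Of 49 tested genes of the actin cytoskeleton, 23 were lower in shTRMT6, 25 did not pass and 1, TMSB4X, was higher. The median log2 fold change was -0.78, and -1.26 with median scaling, where 31 were lower and none higher. RAP1B (-2.27), TAGLN2 (-1.98), DSTN (-1.79) and ARPC3 (-1.67) were lower, as were the actins ACTB (-1.43) and ACTG1 (-1.46). Of 406 tested genes with symbols that start with ZNF, mostly zinc finger transcription factors, 202 were higher and 1, ZNF22, lower (median 1.06; with median scaling 0.58, 128 higher and 6 lower). Of 35 splicing factors of the SR family, CLK kinases and genes known for transcripts held in the nucleus, 23 were higher and 2, SRSF2 and SRSF3, lower (median 1.63; with median scaling 1.15, 21 higher and 3 lower). CLK4 (2.58), LENG8 (2.92), CCNL2 (2.70) and WSB1 (3.26) were among the higher ones. These lists were built from genes seen to change, so their direction is not independent evidence.

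RPS10-NUDT3, an annotated readthrough of neighbouring genes that shares sequence with RPS10, had 395, 634 and 870 FPKM in the control libraries and was listed at 0 in all 3 knockdown libraries. RPS10 itself had a log2 fold change of -0.57.

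The fall of replication-dependent histones was weighed against 4 explanations. With the trends with level and coding length removed the histone median was -1.61 (SD of members 0.51), and with GC content removed as well it was -1.71, which argues against these biases as the whole cause. A changed division of reads among near-identical copies leaves a family sum alone, but the sum changed by -2.03 on the log2 scale. Fewer cells in S phase remain open. With trends removed the median of 57 replication and S phase genes was -0.62, with 16 lower and 1 higher. That list then passed camera at a correlation of 0.01 (adjusted p = 0.000238) but not with an estimated correlation (camera p = 0.287). In the main fit the histone list did not pass camera with an estimated correlation either (adjusted p = 0.234). An effect of TRMT6 loss on histone translation, or on histone mRNA, also remains a hypothesis, since these values do not separate mRNA from translation.

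For the mitochondrial rise, MT-ATP8 alone was not the source, since the class without it was 6.23 times higher. The share varied 2.56 times among the control libraries alone, and the lowest knockdown share was 3.83 times the highest control share. The labels give no preparation batch, so no test of library preparation was made. An effect of the knockdown on mitochondrial translation stays open, untested.

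The slope, with low and long genes higher and abundant and short genes lower, was weighed against 2 explanations. A difference in depth is argued against, since estimated reads overlapped between groups, with a ratio of means of 0.962 (shTRMT6 to shControl). For background over the whole genome, 400 olfactory receptor genes gained 0.0167 FPKM per gene on average, from 0.0068 to 0.0235 FPKM. The lowest of 10 bins of tested genes gained a median of 1.43 FPKM. This argues against an equal background of that size on every gene, but not against a far smaller one or one on expressed genes only. Tested genes had to reach 1 FPKM in at least 3 libraries and olfactory receptor genes did not, so the gains are not like for like. A translational difference by gene length stays open, untested.

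Beside the slope, 6691 genes with an annotated retained-intron transcript had a median log2 fold change 0.113 above that of 4810 others with trends removed (permutation p = 1e-04, the smallest that 10000 permutations give). Since the slope was removed first, this difference does not bear on its cause, and fragments of unspliced nuclear RNA stay untested as a source of the slope. Genes are not independent replicates.

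A hypothesis that mRNAs with histone-like codon use lost footprints was tested across 11438 genes outside the histone lists. Codon similarity to the histones was compared with the log2 fold change, trends removed. Spearman's rho was 0.0614 and Pearson's r 0.0419 across genes (permutation p = 1e-04 for rho, the smallest possible). Both are opposite in sign to the fall the hypothesis needs, and genes are not independent replicates. Since the trends were removed first, an effect of codon use that runs along level or length would not show here.

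The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 4115 genes and the highest other split 1, and 1 of 10 splits reached the real value. The histone median was 2.01 in size in the real split and at most 1.11 in the others, again 1 of 10. For lists, the real split passed 15 and another split passed 20, and 5 of 10 splits passed at least 15. Camera with a preset correlation thus passed many lists between mixed groups too, where almost no single gene passed. Every split other than the real one mixes libraries of both groups, which leaves part of the real difference and widens the spread within groups. The low gene counts there follow from the mixing, and lists that pass there may be real or false. These splits therefore do not measure what chance alone gives.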
